A study of Danio rerio with 6 samples.

How the data were processed

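ATAC-seq maps open chromatin by letting a transposase insert sequencing adapters where DNA is accessible. It was run on nuclei from Tg(fli1a:egfp) zebrafish embryos at 24 hours post fertilization, sorted by fluorescence into a GFPplus fraction (endothelial nuclei, per the labels) and a GFPminus fraction (non-endothelial nuclei, per the labels). Each library was made from 20000 nuclei, per the labels' protocols. There were 6 libraries, 3 per fraction, and the series' design text describes them as biological triplicates collected on 3 occasions.

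The submitters' processing notes name cutadapt 1.3, Bowtie2 2.1.0, deepTools and MACS2, and the genome build Zv9 (danRer7). The settings of these tools, the peak threshold and any filter on reads are not given in the sources used here. The authors deposited 1 peak list per library, in the narrowPeak layout, and the file headers name danRer7 and a single library each, so peaks were called per library and not on pooled reads. Per the file headers and the layout, each peak carries a fold enrichment at its summit (a ratio over the caller's background), a −log10 p, a −log10 q, a score and a summit offset. The deposited score equals the whole part of 10 times the −log10 q for 99.99% of the 454383 peaks. The lowest deposited −log10 q of each list lay between 1.30 and 1.31, which corresponds to q = 0.05. These scores are the authors' own values, and they were used only to describe, rank or filter peaks within a list. A peak list holds no reads, so the read depth where no peak was called is unknown, and a region without a peak may still hold reads. At summits the pileup could be inferred for part of the peaks only, as described below. No test was run on scores between libraries.

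The relative depth of the libraries was described from the deposited fold values. For peaks tested against the genome-wide background, the fold equals (pileup + 1) / (background rate + 1), so these values are whole multiples of 1 step. That step gave the background rate, for which 13.1% to 30.3% of the peaks of a list gave whole pileups within 0.0002. A Poisson tail computed from this rate returned the deposited −log10 p within 0.02 for 99.48% to 99.98% of those peaks, depending on the library. The rate was divided by the shortest peak of the list, and set relative to the deepest library. That the shortest peak is the length to which the caller extended each fragment is an assumption, so these depths are estimates and no test rests on them alone.

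Peaks of all 6 lists that overlapped by at least 1 bp were merged into 187225 union regions (median 210 bp, longest 2642 bp). A region was GFPplus-only when it held a peak in 3 of 3 GFPplus and in 0 of 3 GFPminus libraries, and GFPminus-only in the opposite case. No test per region was run, because 3 libraries against 3 cannot give a p below 0.1. The summed count of both kinds was set against the other 9 splits of the 6 libraries into 3 and 3. Sharing between libraries was measured with the Jaccard index (bases in both lists over bases in either), and the mean within fractions minus the mean between them was tested with an exact two-sided permutation test over the 10 splits (smallest p 0.1). Numbers of regions per 100 kb window of the 25 numbered chromosomes were compared with 10000 random draws of the same number of union regions within each chromosome. Chromosomes were compared by Fisher's exact test with Benjamini-Hochberg adjustment over 25. Neighbour distances between region midpoints were compared with 1000 draws, within chromosomes, from regions called in at least 3 libraries, with a two-sided permutation p. This comparison was added after the lists had been examined. Regions are not independent replicates in these tests.

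The rule for named items, fixed before the data were examined, took the 5 regions of each kind with the highest value of the lowest −log10 p among their 3 libraries, and the 3 windows of 100 kb with most regions of each kind. Genes, exons, introns and motifs were not analysed here: the gene table at hand is of GRCz12tu, the lists are in Zv9, and coordinates of different builds were not mixed. The gene lists and motifs fixed beforehand were therefore not tested, and items are named by position. Coordinates are 1-based.

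Alternatives were a −log10 q or a fold of at least 5, lists shortened to their best 33437 peaks by −log10 p (the length of the shortest list, here called lists of equal length; GFPminus replicate 3 then keeps its whole list, down to a −log10 p of 3.31, where the other lists end between 6.57 and 9.97), summits widened by 100 bp to each side, an overlap of at least 50% of the shorter peak, numbered chromosomes only, calls in at least 2 of 3 libraries, each library or number left out, and a replicate block. Further alternatives, chosen after the data had been seen, are given as such with their values.

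The code was tested on simulated data. In lists simulated on the 187225 union regions with library labels shuffled and 200 regions of each kind planted, 100.0% of both kinds were recovered. The merged regions and the Jaccard index equalled those of bedtools. A planted window of 12 regions was found (permutation p = 0.002), and 100 planted neighbour pairs gave a permutation p = 0.01, while random regions gave permutation p values of 1.0 and 0.318 in these tests, which used 500 and 200 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used.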

Results

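Open chromatin was profiled by ATAC-seq in sorted nuclei of zebrafish embryos that carry the Tg(fli1a:egfp) transgene, in which regulatory sequence of the ETS transcription factor gene fli1a drives GFP in endothelial cells. Whether all GFPplus nuclei are endothelial was not examined here. The question, as the series title states it, was which regulatory elements are active in the developing endothelium. GFPplus nuclei (3 libraries) were compared with GFPminus nuclei (3 libraries) of embryos at 24 hours post fertilization. The values analysed were the authors' peak calls, made separately in each library.

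The lists held 65602 ± 13179 peaks in GFPplus nuclei (SD, n = 3) and 85859 ± 45420 peaks in GFPminus nuclei (SD, n = 3). In size this difference exceeded the SD of the GFPplus libraries but not that of the GFPminus libraries (exact two-sided permutation p = 0.5, where the smallest possible p is 0.1). GFPplus replicates 1, 2 and 3 had 72695, 73716 and 50396 peaks. GFPminus replicates 1 and 2 had 113476 and 110663 peaks, while GFPminus replicate 3 had 33437. GFPplus minus GFPminus peak numbers ranged from −46467 without GFPminus replicate 3 (exact permutation p = 0.1) to −6448 without GFPminus replicate 1 (exact permutation p = 1.0), in a check added after the numbers had been seen. The depth implied by the peak scores, an estimate, was also highest in GFPminus replicates 1 and 2 and lowest in GFPminus replicate 3. With the deepest library, GFPminus replicate 2, set to 1, it was 0.955 in GFPminus replicate 1, 0.818, 0.815 and 0.427 in GFPplus replicates 1 to 3, and 0.296 in GFPminus replicate 3. The shortest peak was 160 bp in GFPminus replicate 3 and between 108 and 116 bp in the other 5 libraries. Covered sequence was 17.9 ± 4.61 Mb in GFPplus and 22.7 ± 10.5 Mb in GFPminus libraries (SD, n = 3, exact permutation p = 0.6).

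**Figure D1:**
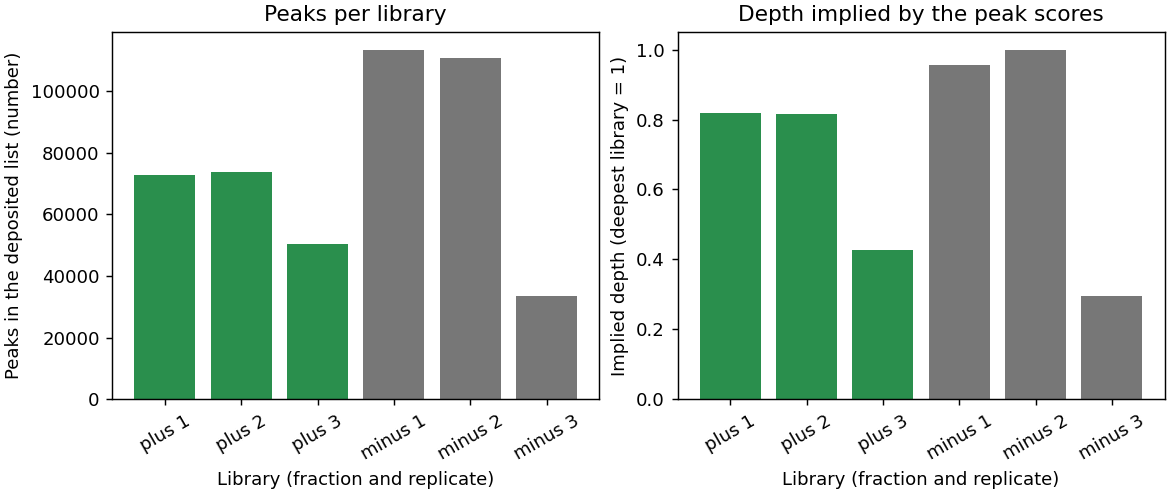
Number of peaks in each deposited list (left) and depth implied by the peak scores, relative to the deepest library (right), 1 bar per library, GFPplus in green and GFPminus in grey. GFPminus replicate 3 is the lowest in both panels, with 33437 peaks and a depth of 0.296.

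The 454383 peaks formed 187225 union regions. Of these, 20275 regions (10.8%) were called in all 6 libraries and 95046 (50.8%) in a single library. Regions called in all 6 were wide and strong, with a median width of 589 bp and a median fold enrichment of 6.82, and their peaks lay at the median 81.2 percentile of −log10 p in their own lists. Regions called in a single library had a median width of 140 bp and a median fold of 3.77, at the 23.3 percentile. Part of this contrast follows from the definition. Merging several peaks widens a region, and a call in all 6 needs a peak in the shortest list. Regions called in all 6 libraries took 63.2% of the peaks of GFPminus replicate 3 and 19.6% of those of GFPminus replicate 1. When each list was shortened to its best 33437 peaks, these shares lay between 43.1% and 45.2% in every library. Each list has a peak in every such region, so these shares follow mostly from list length.

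Libraries of the same fraction shared more open sequence on average than libraries of different fractions once the lists had the same length, although single pairs of both kinds overlapped. The Jaccard index then averaged 0.490 ± 0.052 over the 6 pairs within fractions (SD) and 0.404 ± 0.039 over the 9 pairs between fractions (SD). The highest pair between fractions, GFPplus replicate 2 with GFPminus replicate 2 (0.465), lay above the lowest pair within a fraction, GFPminus replicates 1 and 3 (0.450). The difference of 0.086 was the largest of the 10 splits of the libraries (exact permutation p = 0.1, the smallest possible). On the lists as deposited the difference was 0.040 (0.369 within, 0.329 between), and 1 other split gave as large a value (exact permutation p = 0.2). GFPminus replicate 3 changed sides between these settings. As deposited, its mean Jaccard index was 0.285 with the other GFPminus libraries and 0.333 with the GFPplus libraries, and at equal length it was 0.452 and 0.382. Without GFPminus replicate 3 the difference on the deposited lists was 0.085 (exact permutation p = 0.1). It was 0.012 without GFPplus replicate 3 (exact permutation p = 0.9) and 0.019 without GFPplus replicate 1 (exact permutation p = 0.7).

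**Figure D2:**
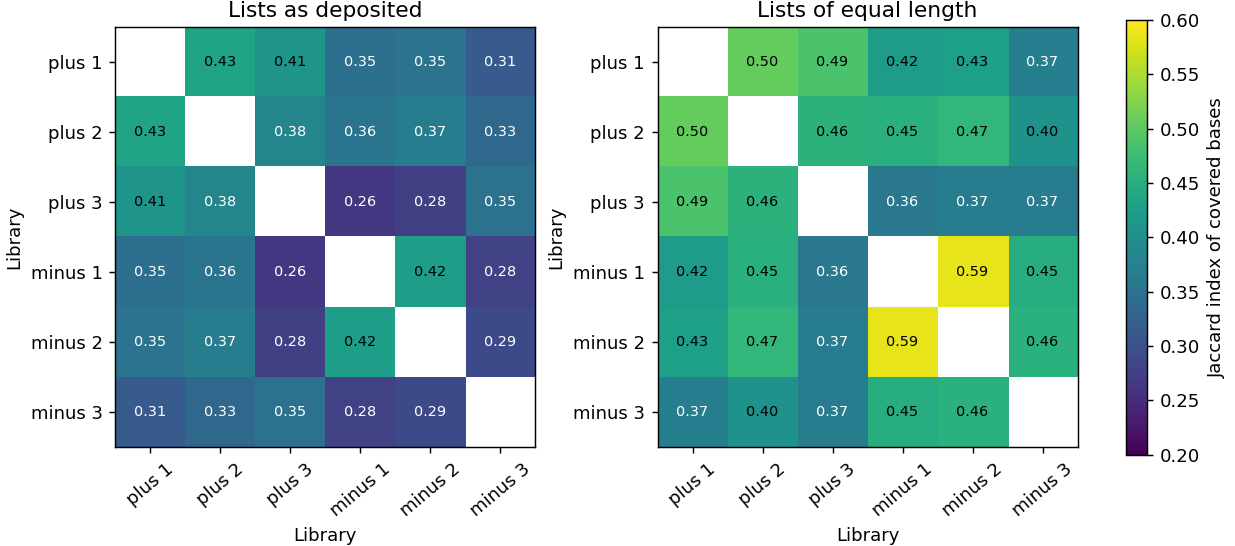
Jaccard index of covered bases for each pair of libraries, with the lists as deposited (left) and shortened to 33437 peaks each (right); rows and columns are the libraries by fraction and replicate, and colour gives the index. At equal length the pairs within fractions average 0.490 and the pairs between fractions 0.404.

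GFPplus nuclei had 2285 regions that were called in all 3 of their libraries and in no GFPminus library, and GFPminus nuclei had 1594 such regions. Both kinds were of middle strength. GFPplus-only regions had a median width of 353 bp and a median fold of 5.23 at the 58.1 percentile of their lists, and GFPminus-only regions a median width of 392 bp and a median fold of 4.76 at the 54.0 percentile. Of the peaks in GFPplus-only regions 4.14% lay in the upper 10% of their list, against 30.2% of the peaks in regions called in all 6 libraries. On the deposited lists with calls in at least 2 of 3 libraries of one fraction and in none of the other, the numbers were 6520 and 15775, so GFPminus then had more. With lists of equal length the numbers were 2267 and 2176, a difference of 91 regions in place of 691. Of the deposited-list regions, 780 GFPplus-only (34.1%) and 546 GFPminus-only regions (34.3%) were also called at equal length. These made up 34.4% of the 2267 and 25.1% of the 2176 regions at equal length, and the other equal-length regions of either kind lay in union regions with a deposited peak of the other fraction.

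The sorted fractions were set against the other ways of dividing the 6 libraries. At equal length the sum of both kinds was 4443 for the sorted fractions and 1106 or fewer for the other 9 splits. The 18 other sets of 3 libraries had a median of 192 regions of their own, and none had more than 752. With the lists as deposited the sorted fractions gave 3879 regions, and 1 other split gave 5254. That split had 5211 regions called in the 3 longest lists (GFPplus replicate 2 and GFPminus replicates 1 and 2) and in none of the other 3. Leaving out 1 library asks for fewer peaks in its own fraction or for fewer lists without a peak, so a count can only rise. GFPplus-only regions numbered 4270 without GFPplus replicate 2 and 4121 without GFPplus replicate 3, and GFPminus-only regions numbered 2910 without GFPplus replicate 2 and 14996 without GFPminus replicate 3, with 2365 GFPplus-only regions in that last case.

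**Figure D3:**
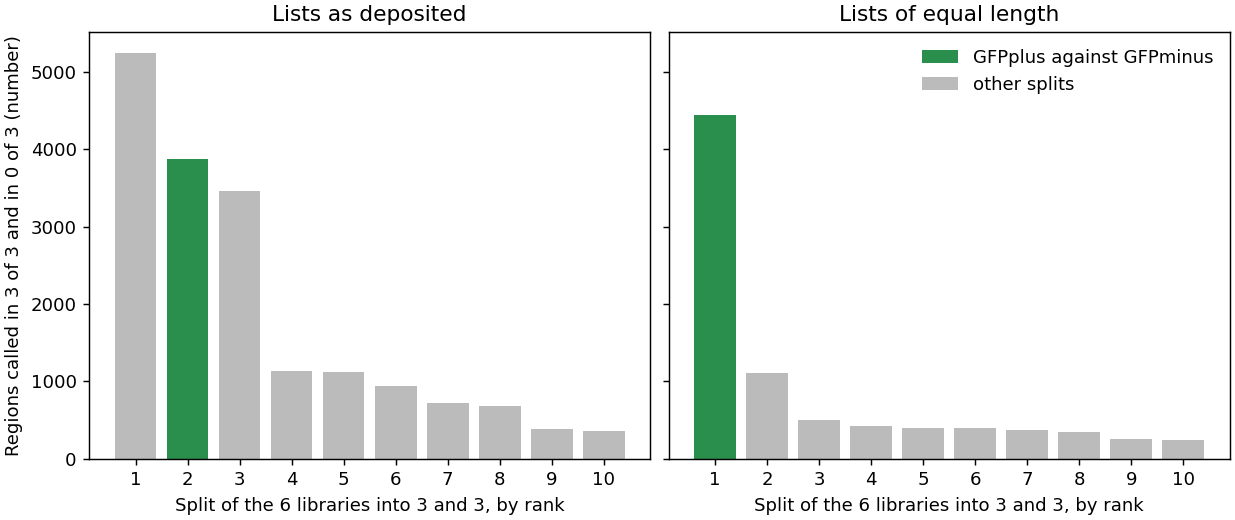
Number of regions called in all 3 libraries of one set and in none of the other, summed over both directions, for the 10 splits of the 6 libraries ranked by that number, with the lists as deposited (left) and of equal length (right). The sorted fractions (green) rank second with 3879 regions on the left and first with 4443 on the right, where the next split has 1106.

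The strongest GFPplus-only region lay on chromosome 15 at 41032618 to 41033433 (Zv9), with a fold enrichment of 15.7 ± 2.00 (SD, n = 3) and a −log10 p of at least 45.5 in each GFPplus library. It ranked between 389 and 1089 in the GFPplus lists and had no peak in a GFPminus list. The next was on chromosome 6 at 94086 to 94378, with a fold of 7.50 ± 0.87 (SD, n = 3) and a −log10 p of at least 34.1. Another on the same chromosome, at 57974011 to 57974781, had a fold of 9.99 ± 1.71 (SD, n = 3). The remaining ones were on chromosome 23 at 37084909 to 37085494, with a fold of 10.6 ± 0.98 (SD, n = 3), and on chromosome 5 at 74793887 to 74794259, with a fold of 8.62 ± 0.54 (SD, n = 3). The strongest GFPminus-only region lay on chromosome 16 at 2493846 to 2494148, with a fold of 14.2 ± 1.88 (SD, n = 3) and a −log10 p of at least 27.7. It was followed by regions on chromosome 15 at 38211234 to 38211909 (fold 7.09 ± 0.61, SD, n = 3), chromosome 20 at 48847078 to 48847504 (7.78 ± 2.24) and at 39984878 to 39985669 (8.82 ± 0.60), and chromosome 19 at 41228540 to 41229051 (8.59 ± 0.11). With summits widened by 100 bp to each side in place of whole peaks, all 10 regions had calls in 3 libraries of one fraction and 0 of the other. This was nearly fixed in advance, since the regions were picked for that pattern and each summit lies within its own peak.

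Regions of one kind were dense in a few 100 kb windows. On chromosome 16 at 21000001 to 21100000, 5 of 8 union regions were GFPplus-only, and on chromosome 6 at 33700001 to 33800000, 5 of 17 were. Either count was at the edge of what random draws gave anywhere in the genome (permutation p = 0.0399 for both). Neither window held a GFPminus-only region or one called in all 6 libraries. On chromosome 2 at 29400001 to 29500000, 6 of 25 union regions were GFPminus-only (genome-wide permutation p = 0.0002) and none was GFPplus-only. The third window for GFPplus (chromosome 19, 29100001 to 29200000, 4 regions, p = 0.554) and the next for GFPminus (chromosome 9, 38700001 to 38800000, and chromosome 1, 30700001 to 30800000, 4 regions each, p = 0.184) did not pass the permutation test. The GFPplus windows did not pass when draws came only from regions called in at least 3 libraries, a setting added after the data had been seen (permutation p = 0.131), and at equal length no GFPplus window passed (permutation p = 0.807 for the densest), while the chromosome 2 window passed in the first case (permutation p = 0.0014). At equal length 4 windows passed for GFPminus-only regions, the densest on chromosome 11 at 43100001 to 43200000 (8 regions, genome-wide permutation p = 0.0001). Draws from regions called in at least 3 libraries were not run at equal length, so these 4 windows did not face them.

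**Figure D4:**
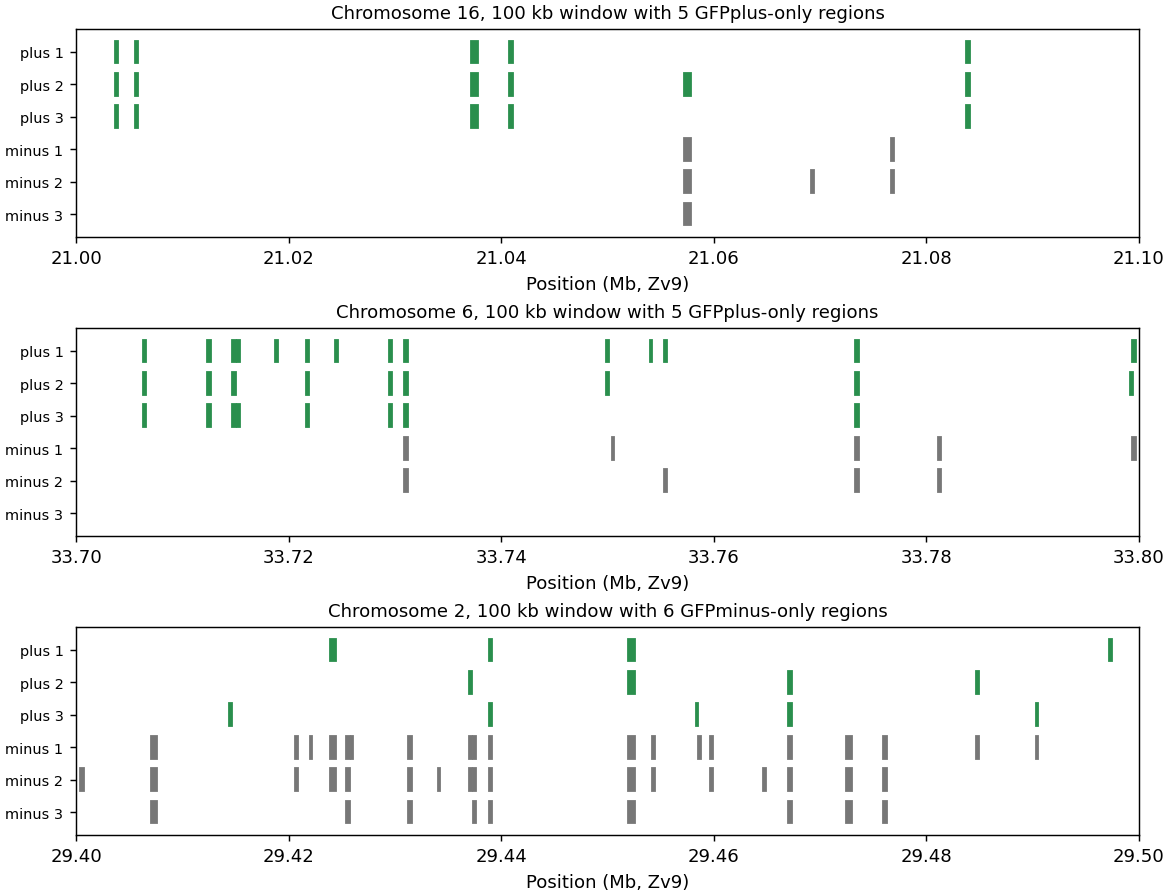
Map of the 3 windows of 100 kb that passed the genome-wide permutation test, with the position in Mb (Zv9) on the x axis and 1 row per library; each box is a union region with a peak in that library (GFPplus green, GFPminus grey), drawn at least 250 bp wide. The 5, 5 and 6 regions of one kind appear as columns with boxes in 3 rows of 1 fraction and none in the other.

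Over the numbered chromosomes there were 2250 GFPplus-only and 1563 GFPminus-only regions, a ratio of 1.44. Chromosome 7 had 108 and 118, a ratio of 0.915 against 1.48 on the other chromosomes (Fisher's exact test, adjusted p = 0.0119). It was the 1 chromosome of 25 that passed, and 6 had an unadjusted p under 0.05. At equal length the ratio on chromosome 7 was 0.661 against 1.08 elsewhere (Fisher's exact test, adjusted p = 0.0029). In a check added after the result had been seen, the call was lost without GFPplus replicate 2 (adjusted p = 0.0943, Fisher's exact test) and without GFPminus replicate 1 (adjusted p = 0.246, Fisher's exact test), with the same direction, and without GFPminus replicate 3 chromosomes 10 and 20 passed beside chromosome 7. On the other chromosomes the ratio ranged up to 2.12 on chromosome 12.

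GFPplus-only regions lay near each other more often than randomly drawn regions, in a comparison added after the lists had been examined. Another GFPplus-only region was 1 to 10 kb away for 10.5% of the 2250 regions, against 4.41% ± 0.59 in the draws (SD, permutation p = 0.002, the smallest that 1000 draws give). For GFPminus-only regions the share was 5.05% against 3.12% ± 0.61 (permutation p = 0.004). With lists of equal length, a setting chosen after these values had been seen, the shares were 11.9% for GFPplus-only and 12.1% for GFPminus-only regions, against 5.08% and 5.03% in the draws (permutation p = 0.002 for both). A GFPminus-only region within 10 kb was found for 2.93% of the GFPplus-only regions, against 3.38% ± 0.38 in the draws (permutation p = 0.268). For a distance of 1 to 10 kb, as used for the same kind, it was 2.93% against 3.08% ± 0.37 (permutation p = 0.783). At equal length the share within 10 kb was 3.27%, below the 5.32% ± 0.47 of the draws (permutation p = 0.002). The distance of 1 to 10 kb was not run there for the other kind.

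**Figure D5:**
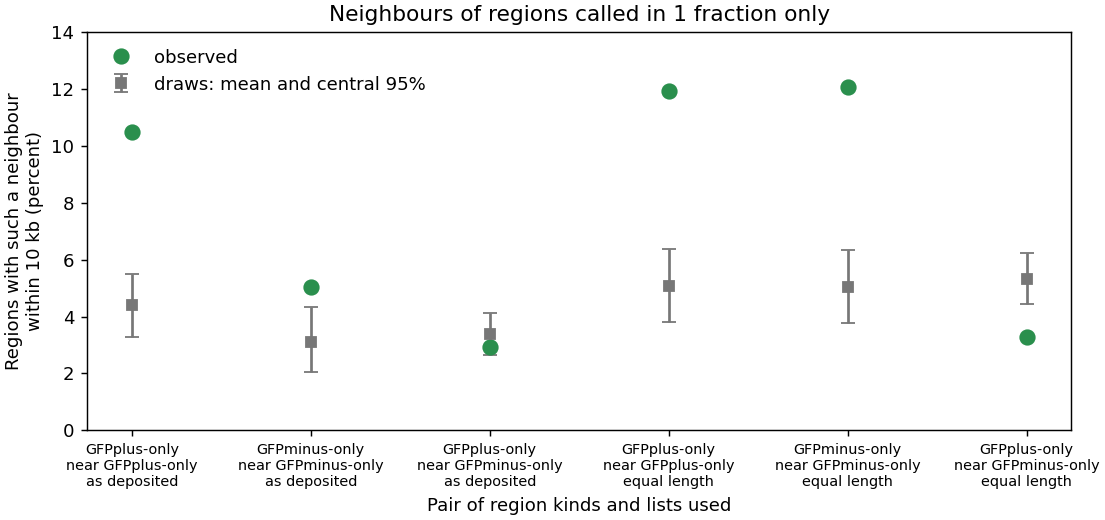
Percent of regions called in 1 fraction only that have a neighbour of the named kind 1 to 10 kb away (same kind) or within 10 kb (other kind), with the lists as deposited and of equal length; circles are the observed shares, squares the mean of 1000 draws, and bars the central 95% of the draws. At equal length both same-kind shares (11.9% and 12.1%) lie above the draws and the share for the other kind (3.27%) lies below.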

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

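The tests chosen only after the data were seen were those requiring best peaks of one fraction, those at equal length with number 3 or GFPminus replicate 3 left out or with a replicate block, draws from regions called in at least 3 libraries, and leave-outs for peak numbers and chromosome 7. Depth limits the calls, because a peak missing from a shallow list does not show closed chromatin. Over the scorings, overlap rules and chromosome sets tried, GFPplus-only regions numbered 1803 to 2405 and GFPminus-only regions 1182 to 2176, within 1.5 times the counts on the deposited lists. With calls in at least 2 of 3 libraries the counts were 6520 and 15775, a difference of −9255 in place of 691. Leaving out a library or a number gave 2365 to 5939 GFPplus-only and 1827 to 16122 GFPminus-only regions; their difference ranged from −12631 to 2499 and turned to −12631 without GFPminus replicate 3 and to −11875 without both libraries numbered 3, where fewer calls are required by construction. The added settings gave 780 and 546 (own peaks among the best 33437, no peak in the full lists of the other fraction), 3783 and 4434 (equal length, number 3 left out, difference −651), and 3644 and 4774 (best 50396, GFPminus replicate 3 left out, difference −1130). The sum for the sorted fractions over that of the highest other split was 0.738 on the deposited lists and turned to 4.02 at equal length, 1.45 with a −log10 q and 2.41 with a fold of at least 5; these filters shorten the long lists most. Windows passing for GFPplus-only regions numbered 2, but 1 with 50 kb windows, 0 at equal length and 0 with draws from regions called in at least 3 libraries; for GFPminus-only regions 1 became 4 at equal length. The cause was not tested. The ratio of chromosome 7 to the others, 0.617, ranged from 0.637 to 0.769 without 1 library and no longer passed at 0.769 (without GFPplus replicate 2) and 0.729 (without GFPminus replicate 1). Apart from the replicate block, where the value is the same by construction, the Jaccard difference (0.012 to 0.086) and the difference in peak numbers kept their direction in each alternative run, though the latter shrank from −20256 to −2880 with a −log10 q of at least 5 (exact permutation p = 0.8). The Jaccard difference on the deposited lists gave exact permutation p values of 0.7, 0.5 and 0.9 without GFPplus replicate 1, 2 or 3, so a kept direction says little there.

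Deviations of the calls were correlated between same-numbered libraries at −0.012, 0.020 and 0.011 (0.0074, 0.028 and 0.064 at equal length), all under 0.1, and not every library correlated best with its own number, so the numbers were not used to pair libraries. Whether a number marks a shared occasion is not known. With the replicate block, regions discordant in all 3 pairs are by construction the same 2285 and 1594, and the Jaccard difference of 0.040 gave an exact permutation p = 0.25 (0.086 and exact permutation p = 0.25 at equal length), the smallest that 3 pairs allow. Within pairs, GFPplus minus GFPminus calls differed by −39799, −36722 and 15168 (exact sign-flip permutation p = 0.5). Gene lists, genomic location and motifs were not run.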

Other observations

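The tests chosen only after the result was seen were those of the mixed split (list length and same-numbered libraries), of list length for GFPminus replicate 3, and of neighbours at equal length; the count over other splits was planned, but what it would show was written down only after it was seen; for same-numbered libraries, for neighbours in mixed sets of libraries, and for fractions lying apart, the rule that decides was changed after the result was seen. The strongest peak of all 6 lists was the same place, chromosome 17 at 53841316 to 53841664 (Zv9), with a fold of 54.0 ± 0.61 (SD, n = 6 libraries) and a −log10 p of 1426 to 2407, while the second strongest peak of any list reached 649. The second strongest peaks of GFPplus replicates 1 and 2 overlapped, on chromosome 18 at 46991067 to 46992400 and at 46991107 to 46991877. In GFPplus replicate 3 the second strongest peak was on chromosome 21 near 34614587. In GFPminus replicates 1 and 2 it was on different unplaced scaffolds, and in GFPminus replicate 3 on chromosome 8 near 451671. At equal length the densest window for GFPminus-only regions was chromosome 11 at 43100001 to 43200000 with 8 regions (genome-wide permutation p = 0.0001, the smallest that 10000 draws give), a window named after its value was seen. It was not set against draws from regions called in at least 3 libraries.

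On the deposited lists a split that mixes the fractions gave 5254 set-specific regions and the sorted fractions gave 3879, so 2 of the 10 splits gave as many; at equal length it was 1 of 10, with 4443 for the sorted fractions and 1106 for the highest other split. With 10 splits the share cannot fall under 0.05. Unequal list length and depth may account for part of the mixed split, since its 3 libraries with 5211 regions are the 3 longest lists and it fell to 1106 at equal length. It was still the highest of the other splits there, where the next had 504 and the median was 395. GFPplus replicate 2 also had a higher Jaccard index with GFPminus replicate 2 (0.465) than with GFPplus replicate 3 (0.457) at equal length. The cause of this remainder was not tested. A shared occasion of same-numbered libraries stays open: the calls hardly deviated together (correlations of at most 0.020 on the deposited lists and 0.064 at equal length), but both libraries numbered 3 had the fewest peaks (50396 and 33437) and the lowest estimated depth (0.427 and 0.296) of their fraction, and this was weighed only after the correlations had been seen. The estimated depths go against lack of depth as the whole cause of fraction-only regions, and the list lengths compare in the same way. By these estimates GFPminus replicate 2 is deeper than each GFPplus library, and each GFPplus library is deeper than GFPminus replicate 3. When own peaks had to be among the best 33437 of their lists, 34.1% of GFPplus-only and 34.3% of GFPminus-only regions were left. Both shares are little over the bound of 30% set beforehand. From GFPminus replicate 3, whose whole list holds 33437 peaks, this demand removed nothing. No share for other regions is set beside these, so they do not decide the question. How much depth adds to fraction-only regions stays open.

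GFPminus replicate 3 overlapped more with GFPplus replicate 3 (Jaccard index 0.349) than with GFPminus replicates 1 and 2 (0.280 and 0.290). List length is a candidate explanation, since at equal length its mean index with the other GFPminus libraries was 0.452 and with GFPplus libraries 0.382. GFPplus nuclei mixed into this library cannot be told apart from a shallow library here: at equal length it called 19.3% of the regions that all 3 GFPplus and neither other GFPminus library called, against 13.9% and 17.3% for GFPminus replicates 1 and 2, a gap too small for either prediction. On the deposited lists it called 3.38%, against 30.8% and 32.9%, and neither setting is free of list length and depth, since at equal length this library keeps its whole list with its weakest peaks. A biological difference between the collection occasions was not tested.

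GFPplus-only regions have other GFPplus-only regions 1 to 10 kb away in 10.5% of cases, and a hypothesis is that elements opened in the same fraction come in clusters; GFPminus-only regions, at 5.05%, were also above their draws. A single element under 1 kb wide, called as several peaks, is argued against. Neighbours closer than 1 kb were left out and the share was still 2.38 times the draws. Wider elements called as several peaks stay open, since they could give neighbours 1 to 10 kb away. Shared calling of nearby regions in any set of libraries was examined in the 7 mixed sets of 3 with at least 500 regions. Together they had 0.926 times the neighbours of the draws (672 against 726). Most of these neighbours came from GFPminus replicates 1 and 2 joined with GFPplus replicate 2 (418) or with GFPplus replicate 1 (176). The limit set beforehand was that none of the 7 sets exceed 1.5 times. It was missed by 1 set at 1.79 times (10 of 532 regions, inside the central 95% of its draws). The pooled value was taken in its place after this was seen. At equal length only 1 mixed set had at least 500 regions, with neighbours for 10 of its 620 regions. The pooled value rests mostly on sets holding the long lists of GFPminus replicates 1 and 2, so it does not decide, and shared calling stays open. The genes at these clusters were not analysed here, and uneven strength of nearby regions stays open.

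A further hypothesis was that the fractions open separate stretches, so that GFPplus-only regions would have fewer GFPminus-only neighbours than drawn regions. On the deposited lists the share was 2.93%, inside the draws. It was 0.867 times the draws from regions called in at least 3 libraries and 1.07 times those from all union regions. For neighbours 1 to 10 kb away these values were 0.954 and 1.21 times. At equal length the share within 10 kb was 3.27%, below the draws from regions called in at least 3 libraries, so the result depends on list length. By the bound set beforehand the deposited lists alone count against the hypothesis; it was left undecided after the opposite result at equal length was seen, since that bound did not allow for list length.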
